A study of Mus musculus with 17 samples.

How the data were processed

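Single cells of the anterior thalamic nuclei of wild-type mice and 3 Visium sections of the same region were measured. Per the labels, the cells were dissected from acute slices, harvested by hand and barcoded at reverse transcription, and the PCR products were pooled by plate. The deposited single-cell table holds raw counts per gene and well, with 52636 genes, 92 spike-in sequences and 11 reporter sequences. The labels name Seurat and the build NCBIM37 without saying what each was used for. They do not state the aligner, the counting step or whether molecules or reads were counted. The deposited well table gives, per the file headers, an animal number (other unit) for each well. The deposited spot table holds raw counts per gene and spot, with 28692 genes (8714 of them at 0 everywhere) and 7827 spots. The deposited spot list gives the section of each spot (other unit), its total count and its number of genes with a count. Total counts per spot equalled the column sums. Per the labels, the sections were 10 µm thick and permeabilized for 24 min, and Space Ranger and Seurat were used, with the builds NCBIM37 and mm10. The spots came without coordinates or region names.

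The well table covers 1344 wells on 14 plates and 3 animals. The 14 labelled single-cell samples could not be matched to the 14 plates by name. The plan fixed before the data were examined would then have pooled all cells as 1 sample without a test. The animal number of the well table was used as the replicate in its place, which departs from that plan. Wells with at least 1000 genes with a count were kept as cells, apart from 9 wells whose source is recorded under another animal (8 of them with enough genes), which left 904 of 1216. The 1000-gene minimum was chosen after the data were seen, and 2 plates gave no cells. Genes with the same symbol kept separate identifiers in the single-cell table (198 symbols were shared by 2 or more identifiers).

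Counts per cell or spot were scaled to 10000, log-transformed, reduced to 2000 variable genes and 30 principal components, and clustered by the Leiden method on 15 neighbours at resolution 0.5 (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0). Figures used matplotlib 3.10.9. Cell clusters carry numbers by size, and cluster 5 was set apart from the neurons by marker lists. Of the 12 spot groups, region 7 was taken as the thalamic region from the marker list of glutamatergic thalamic neurons. It was clustered again by the same steps into subregions, which was decided after the data were seen. Neither boundary follows an anatomical annotation.

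Counts were summed per animal and cluster, or per section and region, where at least 5 cells or spots were present. Sums were tested in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood F test, TMM scaling, filterByExpr and the replicate as a block. Each cluster or subregion was compared with the equally weighted mean of the others, and pairs of clusters were compared in the same fit. P-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The block was checked on the sums. Residual correlation between sums of 1 animal had a median of 0.0616 against -0.0467 for other pairs, and for sections it was 0.174 against -0.0929. Neurons were not tested against other cells, because fewer than 3 animals held 5 cells of cluster 5. The anterior section had no replicate, so the anterior-posterior comparison gave values with exact Poisson 95% intervals. It used genes with at least 50 counts and a 2-fold difference in the same direction in both posterior sections. Intervals cover counting error only.

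Functional lists with at least 5 measured members, 24 of them, were tested with camera (limma 3.58.1) at a correlation of 0.01 on voom values, and again with an estimated correlation and with fry. Benjamini-Hochberg adjustment ran over lists and comparisons together. Older symbols in the lists were looked up through the reference gene tables. The overlap of cluster genes with subregion genes was tested with one-sided Fisher's exact test over the genes tested in both assays. For shares of cells with a count, cells were thinned to 5000 counts, which left out 0, 61 and 2 shallower cells of animals 1, 2 and 3.

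Genes were named by a rule fixed before the data were examined. For each comparison these were the 10 genes with the largest log2 fold change in each direction among those with an adjusted p under 0.05, an absolute log2 fold change of at least 1, a mean of at least 20 CPM on the higher side and 1 direction in all replicates. Added to these were up to 4 members of each list with the smallest adjusted p and a fixed set of thalamic marker genes. The text gives the part of these that bears on each comparison, favouring genes that passed with each replicate left out. Genome positions are from GRCm38.p6 and were found for 173 of 185 named genes. The spot table gives symbols only.

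The tests were checked on simulated data with the same number of replicates and the same depth. The simulation held no animal or section effects and its groups were known beforehand. It therefore does not cover groups defined on the tested counts. The changed genes were drawn from well-expressed genes only, so the recovery rates do not cover weakly expressed genes. With 200 changed genes, the comparison of cluster 4 recovered 25% of 2-fold and 68% of 4-fold changes. Of its 98 calls over 11810 genes, 5 were false. Subregion 5 gave 60% and 92%, with 13 false among 165 calls over 6376 genes. The thalamic region gave 99% and 100%, with 4 false among 203 calls over 13684 genes.

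Alternatives fixed beforehand were scaling by RLE size factors, no low-count filter, no replicate block, the Wald test of DESeq2 1.42.0, leaving out each replicate, sums of at least 10 cells, cells without extreme totals (3 times from the median of their cluster), resolution 1.0, other spots with Tcf7l2 counts above the section median, a minimum of 200 counts, TMM-scaled CPM, a log2 fold change of at least 2 and unthinned shares. Added after the data were seen were cells with at least 2000 genes, leaving out 2 doubtful plates with 98 cells, defining and testing clusters on separate parts of the counts, sums per plate, leaving out 19 cells that carry markers of another type, a mean-based count minimum and equal weights for subregions. RLE scaling moved the median log2 fold change of all genes by less than 0.1 in each comparison.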

Results

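RNA was counted in single cells from the anterior thalamic nuclei of wild-type mice and in 3 brain sections that contain these nuclei. The anterior thalamic nuclei (anterodorsal, anteroventral and anteromedial) are thalamic relay nuclei of the limbic system, tied to head-direction signals and memory. The cells had been harvested by hand into plates. Of 1216 wells with a cell, 904 with at least 1000 genes with a count and 1 animal on record were kept. They came from 3 animals with 103, 328 and 473 cells and total counts of 6264778, 3221635 and 29648927. The median count per cell was 49798 in animal 1 (range 7883 to 186894), 8845 in animal 2 (1892 to 37207) and 50474 in animal 3 (2160 to 304940). The sections were Visium arrays, in which each spot collects RNA from a small patch of tissue. Posterior section 2 held 2794 spots with 26032042 counts, anterior section 5 held 2540 spots with 13788407 counts, and posterior section 6 held 2493 spots with 18582120 counts.

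Clustering divided the cells into 5 clusters. Clusters 1 to 4 were neuron clusters of 439, 208, 191 and 39 cells, of which 9, 3, 7 and 0 carried at least 3 markers of another cell type. These included 5 cells of cluster 1 with markers of pericytes or smooth muscle and 5 cells of cluster 3 with markers of GABA neurons. Cluster 5 was an oligodendrocyte-like cluster of 27 cells. Each of the 4 neuron clusters held at least 6 cells from every animal. Slc17a6 (ENSMUSG00000030500, chromosome 7, 51621830 to 51671126 in GRCm38.p6), which encodes a vesicular glutamate transporter, lay between 835 and 1036 CPM (counts of the gene per 1e6 counts) in the 4 neuron clusters and did not pass the threshold in any of their 4 comparisons with the others, with adjusted p between 0.315 and 0.845.

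The first question was which genes set each neuron cluster apart from the mean of the other 3 neuron clusters. Values are mean CPM ± SD over 3 animals, log2 fold changes ± SE come from edgeR's quasi-likelihood test on sums per animal, and p-values are Benjamini-Hochberg adjusted over 11810 genes. The genes named moved in the same direction in 3 of 3 animals unless stated otherwise. They describe the clusters, because the same counts defined and tested them. The fold change is against the mean of the other clusters on the log scale, so a gene near 0 in 1 of those clusters has a large fitted change. The CPM values show its actual level. The CPM of the other clusters is their plain mean, which 1 high cluster can carry.

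Cluster 1 carried Car4 (ENSMUSG00000000805, chromosome 11, 84957754 to 84966054), which encodes a membrane-bound carbonic anhydrase, at 165 ± 39.2 against 11.4 ± 9.67 CPM (log2 fold change 4.55 ± 0.51, adjusted p = 0.000409). Ccdc141 (ENSMUSG00000044033) was at 201 ± 28.7 against 29.4 ± 6.34 CPM (log2 fold change 3.83 ± 0.55, adjusted p = 0.00244). The fibrillar collagen gene Col27a1 (ENSMUSG00000045672, chromosome 4, 63214009 to 63334991), the gene listed beforehand for anteroventral neurons, was at 461 ± 103 against 204 ± 41.2 CPM (log2 fold change 1.76 ± 0.30, adjusted p = 0.00874). Npsr1 (ENSMUSG00000043659, chromosome 9, 24097912 to 24317590), which encodes the neuropeptide S receptor, gave 681 counts in cluster 1, in 102 of 439 cells, and 1 count in the other 3 clusters together (adjusted p = 0.00188, log2 fold change 9.30 ± 1.08). Among the genes that fell, the calcium-binding protein gene Calb2 (ENSMUSG00000003657, chromosome 8, 110142526 to 110168212) was at 2.41 ± 3.40 against 127 ± 42.0 CPM (log2 fold change -5.13 ± 0.86, adjusted p = 0.00795). Calb1 (ENSMUSG00000028222, chromosome 4, 15881264 to 15906709) fell to 25.6 ± 3.82 against 284 ± 68.1 CPM (adjusted p = 0.00892, log2 fold change -1.57 ± 0.27). In all, 98 genes rose and 48 fell. The number of genes was 729 without animal 1, 26 without animal 2 and 25 without animal 3. Car4 and Ccdc141 passed in each of these 3 fits. Without animal 3 the adjusted p was 0.141 for Npsr1, 0.0884 for Calb2 and 0.603 for Calb1. Without animal 2 it was 0.115 for Col27a1 and 0.235 for Calb1. Npsr1 did not pass in DESeq2 (adjusted p = 0.271). Calb1 did not pass where separate parts of the counts defined and tested the clusters (adjusted p = 0.284).

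Functional gene lists fixed before the data were examined were read in the same fits, with the camera set test. In cluster 1 the voltage-gated potassium channels shifted upward (camera adjusted p = 3.06e-07, adjusted p = 0.0328 with an estimated correlation): 3 of 30 rose, 0 fell and 27 did not pass (11 up and 1 down adjusted over the list alone). Kcnq3 (ENSMUSG00000056258) changed by 2.32 ± 0.28, Kcnb2 (ENSMUSG00000092083) by 1.34 ± 0.29 and Kcnf1 (ENSMUSG00000051726) by 2.07 ± 0.45 on the log2 scale. Genes of cholesterol synthesis shifted downward (camera adjusted p = 1.41e-15, adjusted p = 0.0156 with an estimated correlation): 0 of 18 rose, 3 fell and 15 did not pass (0 up and 9 down adjusted over the list alone). Fdft1 (ENSMUSG00000021273), which encodes squalene synthase, changed by -1.98 ± 0.30, Hmgcs1 (ENSMUSG00000093930) by -0.99 ± 0.19 and Sqle (ENSMUSG00000022351) by -2.11 ± 0.43. Of 18 genes of fast-firing neurons, Cplx1 (ENSMUSG00000033615) rose by 1.01 ± 0.15 and 17 did not pass (8 up and 3 down adjusted over the list alone; camera adjusted p = 0.000559, adjusted p = 0.0502 with an estimated correlation). Of 19 calcium-binding protein genes, S100a10, Calb2 and Calb1 fell and 16 did not pass (1 up and 6 down adjusted over the list alone; camera adjusted p = 0.0440, adjusted p = 0.139 with an estimated correlation). None of the 5 measured cholinergic receptors passed (2 rose and 1 fell adjusted over the list alone), and the list was called upward (camera adjusted p = 0.0475, adjusted p = 0.152 with an estimated correlation) with a median of 0.64 and a mean of -0.05. Immediate early and dissociation stress genes were called upward (camera adjusted p = 0.00543, adjusted p = 0.0609 with an estimated correlation), with a median of 0.71: 0 of 23 rose, 0 fell and 23 did not pass (0 up and 0 down adjusted over the list alone). Cells can turn these genes on while being dissociated, and whether that differed between clusters was not tested. Ribosomal proteins were called downward (camera adjusted p = 0.000126, adjusted p = 0.146 with an estimated correlation), with a median of -0.14: 0 of 59 rose, 0 fell and 59 did not pass (0 up and 0 down adjusted over the list alone).

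Cluster 2 had higher Tnnt1 (ENSMUSG00000064179, chromosome 7, 4504569 to 4515975), a troponin gene also transcribed in thalamic neurons, at 529.6 ± 293 against 122 ± 78.5 CPM (log2 fold change 3.36 ± 0.30, adjusted p = 7.12e-06). The calcium channel subunit gene Cacng4 (ENSMUSG00000020723, chromosome 11, 107732357 to 107794706) was at 319 ± 145 against 89.5 ± 47.0 CPM (log2 fold change 5.23 ± 0.33, adjusted p = 1.34e-06). Calb1, which encodes calbindin, was at 354 ± 31.2 against 174 ± 58.7 CPM (log2 fold change 3.46 ± 0.22, adjusted p = 8.47e-07). Tcf7l2 (ENSMUSG00000024985, chromosome 19, 55741797 to 55933659), a transcription factor gene of thalamic neurons, was at 1082 ± 66.0 against 651 ± 111 CPM (log2 fold change 0.77 ± 0.13, adjusted p = 0.00109). The secreted synaptic protein gene C1ql2 (ENSMUSG00000036907, chromosome 1, 120340582 to 120343174) was nearly absent at 0.219 against 423 CPM (adjusted p = 0.000161, log2 fold change -5.66 ± 0.72). The 423 CPM came mostly from cluster 4, at 957, 1245 and 1549 CPM in animals 1, 2 and 3. Cluster 3 held 0, 4.27 and 0.578 CPM, so the low level is not particular to cluster 2. The neuropeptide gene Gal (ENSMUSG00000024907) was at 7.70 ± 5.62 against 184 ± 45.0 CPM (log2 fold change -4.82 ± 0.70, adjusted p = 0.000450). The complexin gene Cplx2 (ENSMUSG00000025867) was at 0.666 against 64.7 CPM (adjusted p = 0.000679, log2 fold change -6.28 ± 0.96). In all, 738 genes rose and 672 fell, with 3706, 274 and 336 genes without animals 1, 2 and 3. Of the genes named for cluster 2, Tcf7l2 did not pass without animal 2 (adjusted p = 0.0547) or without animal 3 (adjusted p = 0.0645). The others passed in all 3 of these fits.

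Cluster 2 cells held fewer counts than the other cells (0.724, 0.719 and 0.609 of the median of animals 1, 2 and 3) and a median mitochondrial share of 4.41%, against 3.24%, 1.99% and 2.36% in clusters 1, 3 and 4. The broadest list change in cluster 2 was in mitochondrial oxidative phosphorylation, where 0 of 54 rose, 49 fell and 5 did not pass (0 up and 52 down adjusted over the list alone), camera adjusted p = 1.71e-42, adjusted p = 0.0261 with an estimated correlation. Cox4i1 (ENSMUSG00000031818) changed by -1.78 ± 0.13 and Ndufa4 (ENSMUSG00000029632) by -1.75 ± 0.14 on the log2 scale. Among the cytosolic ribosomal proteins 0 of 59 rose, 16 fell and 43 did not pass (0 up and 19 down adjusted over the list alone), camera adjusted p = 5.82e-11, adjusted p = 0.0450 with an estimated correlation. Rps14 (ENSMUSG00000024608) changed by -1.35 ± 0.19 and Rpl4 (ENSMUSG00000032399) by -1.18 ± 0.17. The voltage-gated calcium channels shifted upward (camera adjusted p = 0.000124, adjusted p = 0.0328 with an estimated correlation): 6 of 18 rose, 0 fell and 12 did not pass (8 up and 0 down adjusted over the list alone). Cacna1g (ENSMUSG00000020866), which encodes a low-threshold channel of thalamic burst firing, rose by 1.87 ± 0.20 and Cacna1a (ENSMUSG00000034656) by 1.16 ± 0.17. Of the ionotropic glutamate receptors 6 of 17 rose, 0 fell and 11 did not pass (8 up and 0 down adjusted over the list alone), camera adjusted p = 0.000366, adjusted p = 0.0502 with an estimated correlation. Grik1 (ENSMUSG00000022935) rose by 4.52 ± 0.76 and Grin2b (ENSMUSG00000030209) by 0.83 ± 0.16. Of the thalamic transcription factors 11 of 45 rose, 0 fell and 34 did not pass (14 up and 0 down adjusted over the list alone), camera adjusted p = 0.000126, adjusted p = 0.0261 with an estimated correlation. Foxp1 (ENSMUSG00000030067) rose by 3.38 ± 0.36 and Hlf (ENSMUSG00000003949) by 1.83 ± 0.29. This list also holds Calb2, which is a calcium-binding protein gene and no transcription factor. Of the fast-firing neuron genes 1 of 18 rose, 6 fell and 11 did not pass (2 up and 7 down adjusted over the list alone), camera adjusted p = 0.0170, adjusted p = 0.0962 with an estimated correlation.

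Among the genes that set cluster 3 apart, Calb2, which encodes calretinin, was at 327 ± 81.2 against 19.0 ± 14.4 CPM (log2 fold change 5.01 ± 0.54, adjusted p = 0.000181). It was counted in 105 of 191 cells. Necab1 (ENSMUSG00000040536, chromosome 4, 14952245 to 15149804), another calcium-binding protein gene, was at 214 ± 74.1 against 25.4 ± 16.7 CPM (log2 fold change 6.09 ± 0.46, adjusted p = 6.91e-06). Calb1 was at 494 ± 177 against 127 ± 9.24 CPM (log2 fold change 4.06 ± 0.22, adjusted p = 1.58e-07). The fibulin gene Fbln1 (ENSMUSG00000006369, chromosome 15, 85205949 to 85286294) was at 85.5 ± 12.7 against 1.83 ± 2.11 CPM (log2 fold change 6.48 ± 0.85, adjusted p = 0.000728), counted in 68 of 191 cells. The neuropeptide gene Cck (ENSMUSG00000032532, chromosome 9, 121489824 to 121495694) was at 1718 ± 470.3 against 972 ± 76.8 CPM (log2 fold change 1.07 ± 0.19, adjusted p = 0.00611). Col27a1 fell to 27.0 ± 14.3 against 349 ± 76.8 CPM (log2 fold change -3.57 ± 0.42, adjusted p = 0.000373). The vesicle release genes Vamp1 (ENSMUSG00000030337) and Cplx1 (ENSMUSG00000033615) were at 96.6 against 320.4 CPM and 458 against 1334 CPM. Gad1 (ENSMUSG00000070880, chromosome 2, 70561303 to 70602014) and Gad2 (ENSMUSG00000026787, chromosome 2, 22621015 to 22693877), genes of GABA synthesis, and Sst (ENSMUSG00000004366) were also called, but 98.1%, 87.2% and 100% of their counts in the cluster lay in 5 cells. In all, 156 genes rose and 33 fell, with 944, 41 and 47 genes without animals 1, 2 and 3. Cck did not pass without animal 2 (adjusted p = 0.0770) or animal 3 (adjusted p = 0.208).

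Of the calcium-binding protein genes in cluster 3, 7 of 19 rose, 0 fell and 12 did not pass (12 up and 1 down adjusted over the list alone), camera adjusted p = 2.66e-10, adjusted p = 0.0156 with an estimated correlation. Rcn1 (ENSMUSG00000005973) rose by 3.53 ± 0.44 on the log2 scale. Among the neuropeptides 3 of 13 rose, 0 fell and 10 did not pass (5 up and 0 down adjusted over the list alone), camera adjusted p = 9.40e-05, adjusted p = 0.0450 with an estimated correlation, and these were Sst, Cck and Scg2 (ENSMUSG00000050711, 2.23 ± 0.46). The median of this list was 0.83, or 0.55 with clusters at 0 counts set to 3 counts. The fast-firing neuron genes were called downward (camera adjusted p = 2.14e-05, adjusted p = 0.0261 with an estimated correlation) although their mean was 0.54 and their median -0.49: 3 of 18 rose, 2 fell and 13 did not pass (4 up and 6 down adjusted over the list alone). The 3 that rose were Spp1 (ENSMUSG00000029304), Kcnc4 (ENSMUSG00000027895) and Pvalb (ENSMUSG00000005716). Of the 1071 Pvalb counts in the cluster, 99.7% lay in 5 of 191 cells. The marker list of GABA neurons rose there too, in 7 of 8 genes. Cadherins and protocadherins went both ways: 6 of 20 rose, 1 fell and 13 did not pass (9 up and 1 down adjusted over the list alone), camera adjusted p = 0.0163, adjusted p = 0.247 with an estimated correlation. Ribosomal proteins were called upward (camera adjusted p = 0.000126, adjusted p = 0.152 with an estimated correlation), with a median of 0.31: 0 of 59 rose, 0 fell and 59 did not pass (0 up and 0 down adjusted over the list alone). So were the receptors of neuropeptides and opioids (camera adjusted p = 0.0127, adjusted p = 0.0962 with an estimated correlation), with a median of 1.00: 0 of 7 rose, 0 fell and 7 did not pass (3 up and 0 down adjusted over the list alone).

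Cluster 4 was marked by C1ql2, which was counted in 39 of 39 cells and stood at 1251 ± 296 against 5.75 ± 1.16 CPM (log2 fold change 9.42 ± 0.34, adjusted p = 4.24e-10). C1ql2 and Serpinb7 (chromosome 1, 107422689 to 107452689) were the genes listed beforehand for anterodorsal neurons. With cells thinned to 5000 counts, a Serpinb7 count was found in 6.48% ± 5.78 of cluster 4 cells (SD, n = 3 animals, none in animal 1) and 0.164% and 0.641% ± 1.11 of the cells of clusters 1 and 3. Unthinned, the shares were 25.5% ± 10.8, 0.349% and 0.575% ± 0.995, and cluster 4 cells are the deeper ones. The muscarinic receptor gene Chrm1 (ENSMUSG00000032773) was at 87.0 ± 9.88 against 1.45 ± 1.96 CPM (log2 fold change 7.47 ± 0.90, adjusted p = 7.17e-05). Slc17a7 (ENSMUSG00000070570, chromosome 7, 45163921 to 45176139), which encodes the vesicular glutamate transporter typical of cortical neurons, was at 133 ± 27.6 against 12.5 ± 8.87 CPM (log2 fold change 3.97 ± 0.54, adjusted p = 0.000194). Calb1 fell to 1.98 against 291 CPM (log2 fold change -5.95 ± 0.40, adjusted p = 3.66e-07), Tnnt1 to 2.98 against 297 CPM and Cck to 333 against 1434 CPM. Cacng4 and Ramp3 (ENSMUSG00000041046) had 0 counts in cluster 4, against 196 and 179.9 CPM in the other clusters. In all, 768 genes rose and 801 fell, with 3564, 539 and 579 genes without animals 1, 2 and 3. C1ql2, Chrm1, Slc17a7, Calb1, Tnnt1 and Cck passed in all 3 of these fits.

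Cluster 4 cells held more counts than the other cells, 2.33, 1.99 and 2.60 times the median of animals 1, 2 and 3. The oxidative phosphorylation genes moved upward in the cluster: 43 of 54 rose, 0 fell and 11 did not pass (52 up and 0 down adjusted over the list alone), camera adjusted p = 1.30e-51, adjusted p = 0.0261 with an estimated correlation. Ndufa4 rose by 1.79 ± 0.12 and Cox4i1 by 1.52 ± 0.11 on the log2 scale. Of the cholesterol synthesis genes 10 of 18 rose, 0 fell and 8 did not pass (14 up and 0 down adjusted over the list alone), camera adjusted p = 5.46e-10, adjusted p = 0.0258 with an estimated correlation. Fdft1 rose by 2.19 ± 0.25 and Msmo1 (ENSMUSG00000031604) by 2.28 ± 0.36. Of the ribosomal proteins 12 of 59 rose, 0 fell and 47 did not pass (15 up and 0 down adjusted over the list alone), camera adjusted p = 5.46e-10, adjusted p = 0.0502 with an estimated correlation. The thalamic transcription factors were called downward (camera adjusted p = 0.000114, adjusted p = 0.0261 with an estimated correlation): 1 of 45 rose, 16 fell and 28 did not pass (1 up and 19 down adjusted over the list alone). Hlf changed by -4.32 ± 0.44 and Mef2a (ENSMUSG00000030557) by -1.25 ± 0.16. Of the potassium channels 1 of 30 rose, 12 fell and 17 did not pass (1 up and 16 down adjusted over the list alone), camera adjusted p = 0.00304, adjusted p = 0.0502 with an estimated correlation. Kcnq3, a subunit of the M-current channel, changed by -5.29 ± 0.47. Of the calcium channels 1 of 18 rose, 7 fell and 10 did not pass (1 up and 9 down adjusted over the list alone), camera adjusted p = 0.0101, adjusted p = 0.0817 with an estimated correlation. The 1 that rose was Cacna1i (ENSMUSG00000022416, 5.18 ± 0.84). Fast-firing neuron genes were called upward (camera adjusted p = 0.000759, adjusted p = 0.0461 with an estimated correlation): 7 of 18 rose, 3 fell and 8 did not pass (7 up and 3 down adjusted over the list alone), among them the neurofilament gene Nefl (ENSMUSG00000022055, 1.27 ± 0.14) and Cplx1 (1.30 ± 0.15). Of 96 list tests over the 4 clusters, 30 passed in camera with a correlation of 0.01, 13 with an estimated correlation and 60 in fry. The fry test asks whether the genes of a list move on balance one way. Without animal 3, 19 of 92 passed. Exchanging the cluster labels within animals gave 30 or more list calls in 6 of 50 splits, the real one included, so chance was not excluded for that number.

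**Figure D1:**
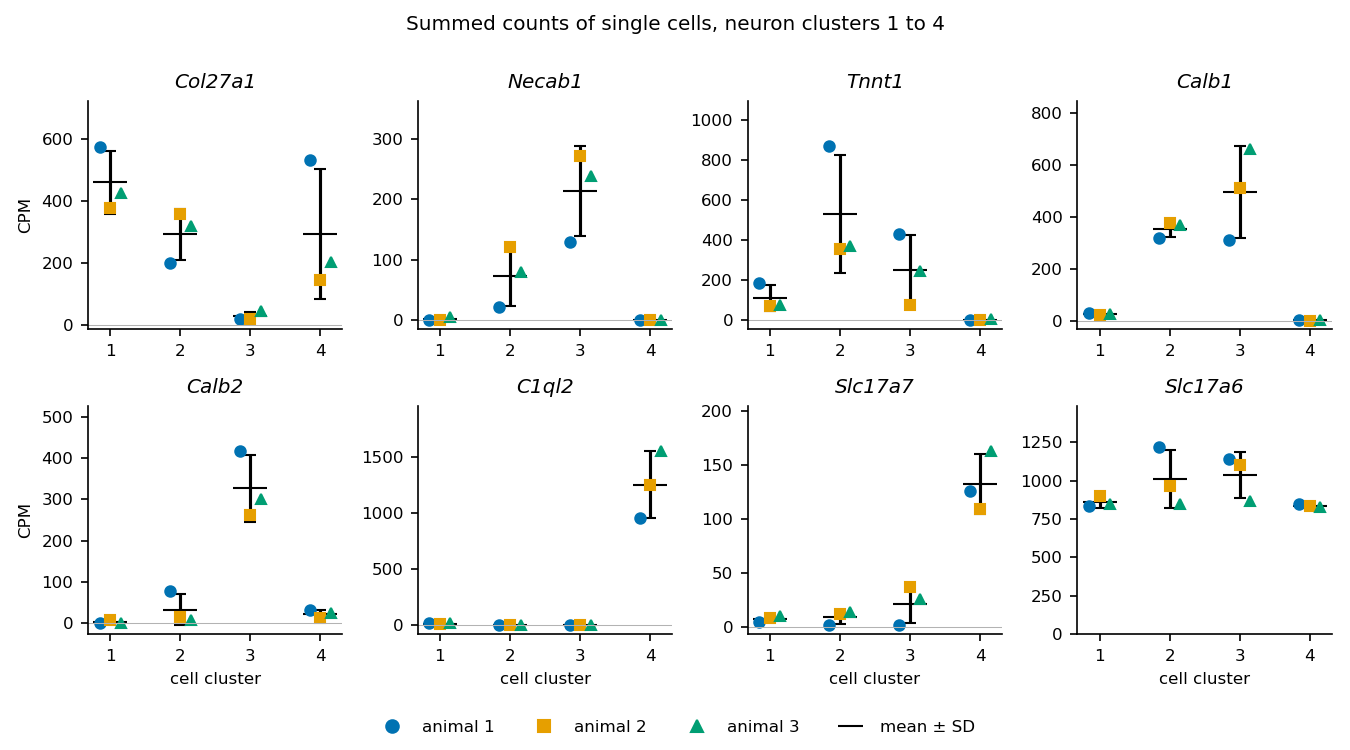
Expression of 8 genes, in CPM, in neuron clusters 1 to 4; each point is 1 animal, horizontal lines give the mean and error bars the SD over 3 animals. C1ql2 stood at 1251 CPM in cluster 4 against 5.75 CPM as the mean of the others, and Calb2 at 327 CPM in cluster 3.

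**Figure D2:**
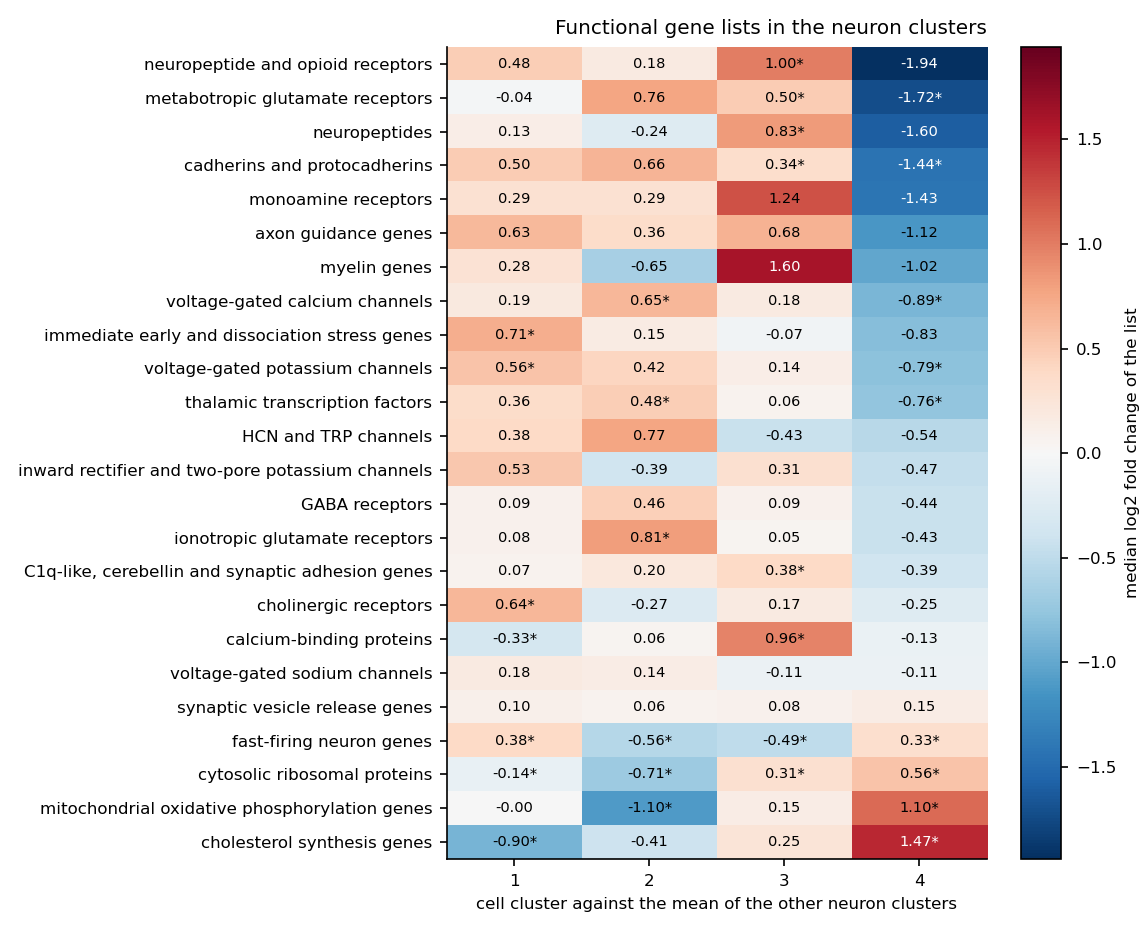
Median log2 fold change of 24 functional gene lists (vertical) in each of the 4 neuron clusters (horizontal) against the mean of the others; a star marks lists that passed in camera with a correlation of 0.01. The oxidative phosphorylation median was -1.10 in cluster 2 and 1.10 in cluster 4, and the cholesterol synthesis median was -0.90 in cluster 1 and 1.47 in cluster 4; setting clusters at 0 counts to 3 counts moved no median by more than 0.42 and turned the sign of 1, that of the ionotropic glutamate receptors in cluster 1 (0.08 to -0.08).

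Pairs of clusters were compared to ask how the neuron groups differ from one another, in the same fit. Between clusters 1 and 2, Gal was at 225 against 7.70 CPM (log2 fold change 5.15 ± 0.75, adjusted p = 0.00210) and Calb1 at 25.6 against 354 CPM (-3.77 ± 0.29, adjusted p = 1.85e-05), each in the same direction in 3 of 3 animals. Col27a1 separated cluster 1 from cluster 3 (461 against 27.0 CPM, 3.99 ± 0.46, adjusted p = 0.000377) but did not pass between clusters 1 and 2 (adjusted p = 0.615). Calb2 was at 2.41 against 327 CPM in clusters 1 and 3 (-7.61 ± 0.95, adjusted p = 0.000713). Cluster 2 against cluster 3 differed in Col27a1 at 292 against 27.0 CPM (3.39 ± 0.45, adjusted p = 0.000721). C1ql2 was at 0.219 against 1251 CPM in clusters 2 and 4 (-11.31 ± 0.63, adjusted p = 1.13e-07), and at 1.62 against 1251 CPM in clusters 3 and 4 (-10.64 ± 0.58, adjusted p = 1.26e-07). Cck was at 1718 against 333 CPM in clusters 3 and 4 (2.42 ± 0.26, adjusted p = 6.35e-05). Without animal 3 the adjusted p for Gal between clusters 1 and 2 was 0.0803.

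The pairs differed in the number of genes called. Clusters 2 and 4 differed in 2182 genes, 1165 of them higher in cluster 2, clusters 1 and 4 in 826 (478 higher in cluster 1), and clusters 3 and 4 in 560 (378 higher in cluster 3). Clusters 2 and 3 differed in 523 genes (160 higher in cluster 2), clusters 1 and 2 in 216 (135 higher in cluster 1), and clusters 1 and 3 in 150 (53 higher in cluster 1). Each count moved by more than 1.5 times when 1 animal was left out. Without animals 1, 2 and 3 they were 1334, 22 and 20 for clusters 1 and 2, 857, 27 and 26 for clusters 1 and 3, 2416, 181 and 173 for clusters 1 and 4, 2177, 45 and 50 for clusters 2 and 3, 4512, 705 and 828 for clusters 2 and 4, and 1695, 140 and 146 for clusters 3 and 4.

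The share of cells with a count of a marker gene was compared after cells had been thinned to 5000 counts each. In clusters 1 to 5, 35, 19, 7, 0 and 2 cells held fewer counts and were left out. C1ql2 was counted in 100% of cluster 4 cells in each of 3 animals, 5.14% ± 2.28 of cluster 1 cells and 1.23% ± 1.07 of cluster 3 cells (SD, n = 3). In the oligodendrocyte-like cluster it was counted in 0 of 25 cells, which allows a share of up to 12% with a count at this depth and sets no limit on cells that express the gene. Calb2 was counted in 41.2% ± 3.62 of cluster 3 cells and 0.621% ± 0.694 of cluster 1 cells. Col27a1 was counted in 69.5% ± 2.06, 46.7% ± 11.6, 6.28% ± 3.07 and 66.7% ± 16.7 of the cells of clusters 1 to 4 and in 16.9% ± 15 of the oligodendrocyte-like cells. The oligodendrocyte-like cells also held counts of genes of thalamic neurons, Slc17a6 in 45.8% ± 3.75 and Tcf7l2 in 44.4% ± 9.62. Only 2 of these cells came from animal 1. Whether their Col27a1 counts stem from oligodendrocytes was not tested. Mbp (ENSMUSG00000041607), a myelin gene, was counted in 97.6% ± 4.12 of the oligodendrocyte-like cells and in 9.56% ± 2.28 of cluster 1 cells.

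The next comparison asked which genes set the thalamic region of the sections apart from all other spots. The region was 1 of 12 groups of spots and held 208, 200 and 249 spots in sections 2, 5 and 6, with 2039882, 985311 and 1710114 counts. Its boundary follows no annotation, and parts of it carried genes of neighbouring tissue, such as Oxt in subregion 2 and Tac2 in subregion 3, so its values are not those of the anterior nuclei alone. Values are mean CPM ± SD over 3 sections, and the genes named moved in the same direction in 3 of 3 sections. Shox2 (ENSMUSG00000027833, chromosome 3, 66971723 to 66981771), a homeobox gene of thalamic relay neurons, was at 279 ± 59.7 against 2.09 ± 0.274 CPM (log2 fold change 7.03 ± 0.10, adjusted p = 3.23e-29). The same counts defined and tested the region. The p-value of Shox2, its highest-ranked leading gene, therefore describes the region and gives no separate support. Gbx2, Tcf7l2 and Slc17a6 belong to the marker list that chose the region, so their rise was expected beforehand and no p-value is given for them. Gbx2 (ENSMUSG00000034486, chromosome 1, 89927962 to 89931176), a gene of thalamic development, was at 95.2 ± 3.70 against 1.31 ± 0.556 CPM (log2 fold change 6.08 ± 0.17), Tcf7l2 at 704 ± 31.7 against 24.2 ± 2.02 CPM (log2 fold change 4.86 ± 0.07) and Slc17a6 at 522 ± 12.1 against 38.9 ± 8.45 CPM (log2 fold change 3.76 ± 0.09). C1ql2 and Col27a1 were higher in the region as well, at 58.7 ± 12.5 against 5.71 ± 2.33 CPM and 36.6 ± 14 against 3.65 ± 0.702 CPM. Gad1 was at 67.1 ± 27.0 against 359 ± 12.2 CPM (log2 fold change -2.48 ± 0.13) and Slc17a7 at 129 ± 35.0 against 502 ± 53.4 CPM (log2 fold change -1.97 ± 0.10). Cck did not pass (adjusted p = 0.0883, log2 fold change 0.14 ± 0.06). Of 13684 genes, 2143 rose and 2181 fell.

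The list of glutamatergic thalamic neurons had served to choose the region, so the rise of all its 13 genes there was expected beforehand, among them Ntng1 (3.93 ± 0.07 on the log2 scale) and Zic1 (3.49 ± 0.07). All 9 cortical and all 7 striatal neuron genes fell, the latter with Ppp1r1b at -3.47 ± 0.13. Of the myelin genes 0 of 17 rose, 16 fell and 1 did not pass (0 up and 16 down adjusted over the list alone), camera adjusted p = 3.50e-09, adjusted p = 0.430 with an estimated correlation. Mal changed by -0.51 ± 0.07. Of the cholesterol synthesis genes 13 of 18 rose, 1 fell and 4 did not pass (13 up and 1 down adjusted over the list alone), camera adjusted p = 1.19e-05, adjusted p = 0.430 with an estimated correlation. Pmvk rose by 0.83 ± 0.09 and Hmgcs1 by 0.51 ± 0.07. The thalamic transcription factors went both ways: 23 of 53 rose, 19 fell and 11 did not pass (23 up and 20 down adjusted over the list alone). Of the neuropeptides 3 of 25 rose, 16 fell and 6 did not pass (4 up and 16 down adjusted over the list alone), and Penk, which encodes enkephalin, changed by -4.03 ± 0.21. Of 24 lists tested, 11 passed in camera and 17 in fry; with an estimated correlation the lowest adjusted p was 0.430, and 1 list had an unadjusted p under 0.05.

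Clustering the 657 thalamic spots alone divided them into 5 subregions of 187, 153, 148, 127 and 42 spots. The question was which genes differ among parts of the region, each subregion being compared with the mean of the other 4 over 6376 genes. As with the cell clusters, the genes describe subregions that the same counts defined, and each gene named moved in the same direction in 3 of 3 sections. When the subregions were defined on 1 part of the counts and tested on the rest, subregions 1 and 5 came back with 145 of 187 and 40 of 42 spots. Subregions 2, 3 and 4 did not come back as groups of their own. Of subregions 2 and 4, 137 of 153 and 122 of 127 spots lay together in 1 group of 363 spots. That group also held 69 spots of subregion 3. The group matched to subregion 1 held 236 spots, 70 of them from subregion 3. The groups that served as reference differed as well, so the comparison was not the same one. In that setting the adjusted p was 0.0778 for Col27a1, 0.0761 for Gad1 and 0.773 for Gbx2 in subregion 1 and 0.346 for Tcf7l2 in subregion 5.

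Subregion 1 had Col27a1 at 96.9 ± 51.2 against 27.2 ± 1.63 CPM (log2 fold change 2.26 ± 0.28, adjusted p = 3.04e-10) and Car4 at 80.2 ± 11 against 23.3 ± 4.88 CPM (log2 fold change 1.79 ± 0.26, adjusted p = 6.26e-08). The potassium channel gene Kcnf1 was at 133 ± 24.4 against 34.3 ± 13.4 CPM (log2 fold change 1.90 ± 0.21, adjusted p = 7.89e-12). Nexn, an actin-binding protein gene, was at 185 against 43.0 CPM. Gad1 rose as well, at 134 ± 68.0 against 49.3 ± 19.8 CPM (log2 fold change 1.62 ± 0.22, adjusted p = 4.92e-09). At resolution 1.0, 19, 12 and 8 spots of the subregion in sections 2, 5 and 6 lay in a group led by Pvalb. That group had Pvalb at 304 CPM and Gad1 at 159 CPM. How far these spots carry the values of subregion 1 was not tested. Calb2 fell to 114 ± 59.0 against 762 ± 8.57 CPM (log2 fold change -2.16 ± 0.15, adjusted p = 2.35e-21), and Gbx2 to 20.5 against 118 CPM. In all, 390 genes rose and 273 fell, with 425 genes without section 2 and 413 genes without section 5. The myelin list shifted upward: 17 of 17 rose, 0 fell and 0 did not pass (17 up and 0 down adjusted over the list alone), camera adjusted p = 1.47e-35, adjusted p = 0.0129 with an estimated correlation. Mobp rose by 1.11 ± 0.09. Of the potassium channels 11 of 26 rose, 0 fell and 15 did not pass (12 up and 3 down adjusted over the list alone), camera adjusted p = 2.80e-06, adjusted p = 0.0256 with an estimated correlation. Of the cholesterol synthesis genes 0 of 15 rose, 6 fell and 9 did not pass (0 up and 7 down adjusted over the list alone), camera adjusted p = 5.89e-06, adjusted p = 0.0233 with an estimated correlation. Of the fast-firing neuron genes 7 of 15 rose, 0 fell and 8 did not pass (8 up and 1 down adjusted over the list alone), camera adjusted p = 2.06e-07, adjusted p = 0.0699 with an estimated correlation. Cplx1 rose by 1.04 ± 0.09.

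Subregion 2 had Necab1 at 474 ± 147 against 221 ± 43.2 CPM (log2 fold change 2.09 ± 0.15, adjusted p = 9.23e-22) and Calb2 at 1037 ± 169 against 531 ± 27.9 CPM (log2 fold change 1.69 ± 0.11, adjusted p = 1.67e-25). Lypd1, which encodes a modulator of nicotinic receptors, was at 142 ± 9.01 against 42.7 ± 12.3 CPM (log2 fold change 1.90 ± 0.22, adjusted p = 1.58e-11). The oxytocin gene Oxt, typical of hypothalamic neurons, was at 1000 ± 1447 against 31.4 ± 27.6 CPM (log2 fold change 5.09 ± 0.17). Col27a1 fell to 4.50 ± 4.13 against 50.3 ± 13.5 CPM (log2 fold change -2.76 ± 0.52, adjusted p = 4.36e-05), and Slc17a6 to 426 against 605 CPM (adjusted p = 0.0541 without section 2). In all, 279 genes rose and 188 fell, with 199 genes without section 2 and 311 genes without section 5. Of the cytosolic ribosomal proteins 29 of 61 rose, 0 fell and 32 did not pass (44 up and 0 down adjusted over the list alone), camera adjusted p = 6.31e-30, adjusted p = 0.0337 with an estimated correlation. Rpl9 rose by 0.63 ± 0.09 on the log2 scale. Of the neuropeptides 3 of 9 rose, 0 fell and 6 did not pass (6 up and 1 down adjusted over the list alone), camera adjusted p = 0.00136, adjusted p = 0.0337 with an estimated correlation. Scg2 rose by 1.00 ± 0.12. Of the synaptic vesicle release genes 2 of 28 rose, 9 fell and 17 did not pass (3 up and 9 down adjusted over the list alone), camera adjusted p = 0.000247, adjusted p = 0.0409 with an estimated correlation.

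Subregion 3 had Tnnt1 at 248 ± 59.3 against 59.5 ± 7.69 CPM (log2 fold change 2.62 ± 0.20, adjusted p = 5.16e-20) and Ramp3, which encodes a co-receptor of the calcitonin family, at 248 ± 33.1 against 86.7 ± 23.4 CPM (log2 fold change 2.01 ± 0.19, adjusted p = 1.29e-14). Calca, the gene of calcitonin and its related peptide, was at 66.3 ± 15.8 against 22.2 ± 4.10 CPM (log2 fold change 2.82 ± 0.44, adjusted p = 2.15e-06). Prkcd (ENSMUSG00000021948, chromosome 14, 30595353 to 30626414), a protein kinase gene of first-order thalamic nuclei, was at 359 ± 94.3 against 117 ± 82.4 CPM (log2 fold change 1.64 ± 0.16, adjusted p = 5.35e-14). Calb1 was at 383 against 230.3 CPM. Tcf7l2 rose to 873 against 705 CPM (adjusted p = 0.00406, or 0.138 without section 6). The subregion also took in the 8 spots of a medial habenula group found at resolution 1.0, and over its pooled spots the highest ratio to the others was that of the habenula gene Tac2 (141 CPM), which was chosen after its values were seen and was not tested between subregions. In all, 179 genes rose and 82 fell, with 166, 141 and 148 genes without sections 2, 5 and 6. Of the thalamic transcription factors 10 of 38 rose, 0 fell and 28 did not pass (10 up and 1 down adjusted over the list alone), camera adjusted p = 0.000102, adjusted p = 0.0256 with an estimated correlation. Foxp1 rose by 1.50 ± 0.19 and Rora by 0.64 ± 0.12 on the log2 scale. Among the genes of C1q-like, cerebellin and synaptic adhesion proteins 4 of 17 rose, 1 fell and 12 did not pass (4 up and 1 down adjusted over the list alone), camera adjusted p = 0.000134, adjusted p = 0.0242 with an estimated correlation. Cbln1 rose by 1.58 ± 0.14. Of the calcium channels 3 of 18 rose, 0 fell and 15 did not pass (5 up and 0 down adjusted over the list alone), camera adjusted p = 0.00278, adjusted p = 0.0360 with an estimated correlation, among them Cacng4 (1.32 ± 0.18). Of the oxidative phosphorylation genes 0 of 54 rose, 5 fell and 49 did not pass (0 up and 6 down adjusted over the list alone), camera adjusted p = 1.11e-14, adjusted p = 0.0672 with an estimated correlation.

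Subregion 4 had Calb2 at 1483 ± 199 against 419 ± 65.0 CPM (log2 fold change 2.38 ± 0.10, adjusted p = 6.71e-39) and Necab1 at 556 ± 111 against 200.5 ± 50.4 CPM (log2 fold change 2.45 ± 0.14, adjusted p = 3.11e-28). Fbln1 was at 124 ± 24.4 against 27.5 ± 5.25 CPM (log2 fold change 2.57 ± 0.24, adjusted p = 2.41e-15). The transcription factor gene Foxp2 was at 166 ± 35.4 against 31.1 ± 7.37 CPM (log2 fold change 3.04 ± 0.24, adjusted p = 2.26e-19). The collagen gene Col12a1 was at 64.4 against 7.71 CPM. Slc17a6 rose to 722 against 531 CPM (adjusted p = 0.000140, log2 fold change 0.45 ± 0.09). Cplx1 fell to 236 ± 68.7 against 842 ± 168 CPM (log2 fold change -1.60 ± 0.12, adjusted p = 1.70e-21). In all, 328 genes rose and 279 fell, with 311 genes without section 2. Of the fast-firing neuron genes 1 of 15 rose, 13 fell and 1 did not pass (1 up and 14 down adjusted over the list alone), camera adjusted p = 4.72e-17, adjusted p = 0.0242 with an estimated correlation. The neurofilament genes Nefm and Nefh changed by -1.59 ± 0.15 and -1.11 ± 0.16 on the log2 scale. Of the myelin genes 0 of 17 rose, 16 fell and 1 did not pass (0 up and 16 down adjusted over the list alone), camera adjusted p = 5.08e-21, adjusted p = 0.0233 with an estimated correlation. Of the calcium-binding protein genes 7 of 20 rose, 2 fell and 11 did not pass (8 up and 3 down adjusted over the list alone), camera adjusted p = 0.000849, adjusted p = 0.0463 with an estimated correlation.

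Subregion 5 had C1ql2 at 509.8 ± 40.3 against 12.9 ± 7.85 CPM (log2 fold change 5.14 ± 0.21, adjusted p = 3.52e-39) and Slc17a7 at 632 ± 4.69 against 82.5 ± 34.5 CPM (log2 fold change 2.97 ± 0.17, adjusted p = 1.20e-29). Rspo3, which encodes an activator of Wnt signalling, was at 100.2 against 6.07 CPM and Chrm1 at 63.6 against 4.07 CPM. Necab1 fell to 14.6 ± 5.77 against 336 ± 76.2 CPM (log2 fold change -4.09 ± 0.36, adjusted p = 3.58e-17), Calb1 to 20.4 against 321 CPM and Tcf7l2 to 484 against 802 CPM. In all, 484 genes rose and 396 fell, with 540 genes without section 6. Its spots held more counts than those of the other subregions, with medians of 13515, 7635 and 11529 in sections 2, 5 and 6 against at most 10880, 5128.5 and 7700. Of the oxidative phosphorylation genes 39 of 54 rose, 0 fell and 15 did not pass (45 up and 0 down adjusted over the list alone), camera adjusted p = 1.40e-33, adjusted p = 0.0242 with an estimated correlation. Ndufa4 rose by 1.34 ± 0.08 on the log2 scale. Of the fast-firing neuron genes 8 of 15 rose, 2 fell and 5 did not pass (10 up and 2 down adjusted over the list alone), camera adjusted p = 2.93e-12, adjusted p = 0.0337 with an estimated correlation. Cplx1 rose by 1.87 ± 0.10. Of the synaptic vesicle release genes 10 of 28 rose, 4 fell and 14 did not pass (10 up and 5 down adjusted over the list alone), camera adjusted p = 0.000276, adjusted p = 0.0436 with an estimated correlation. Vamp1 rose by 2.27 ± 0.15 and Snap25 by 1.34 ± 0.07. Of the cholesterol synthesis genes 9 of 15 rose, 0 fell and 6 did not pass (11 up and 0 down adjusted over the list alone), camera adjusted p = 9.66e-07, adjusted p = 0.0233 with an estimated correlation. The thalamic transcription factors were called downward: 0 of 38 rose, 10 fell and 28 did not pass (2 up and 12 down adjusted over the list alone), camera adjusted p = 0.000469, adjusted p = 0.0337 with an estimated correlation. Foxp1 changed by -2.55 ± 0.39. Immediate early and dissociation stress genes were called upward in subregion 4 (4 of 11 rose, 0 fell and 7 did not pass (5 up and 0 down adjusted over the list alone), camera adjusted p = 8.70e-05, adjusted p = 0.118 with an estimated correlation) and downward in subregion 5 (0 of 11 rose, 2 fell and 9 did not pass (0 up and 2 down adjusted over the list alone), camera adjusted p = 0.00398, adjusted p = 0.227 with an estimated correlation). Over the 5 subregions, 53 of 100 list tests passed in camera, 23 with an estimated correlation and 55 in fry.

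**Figure D3:**
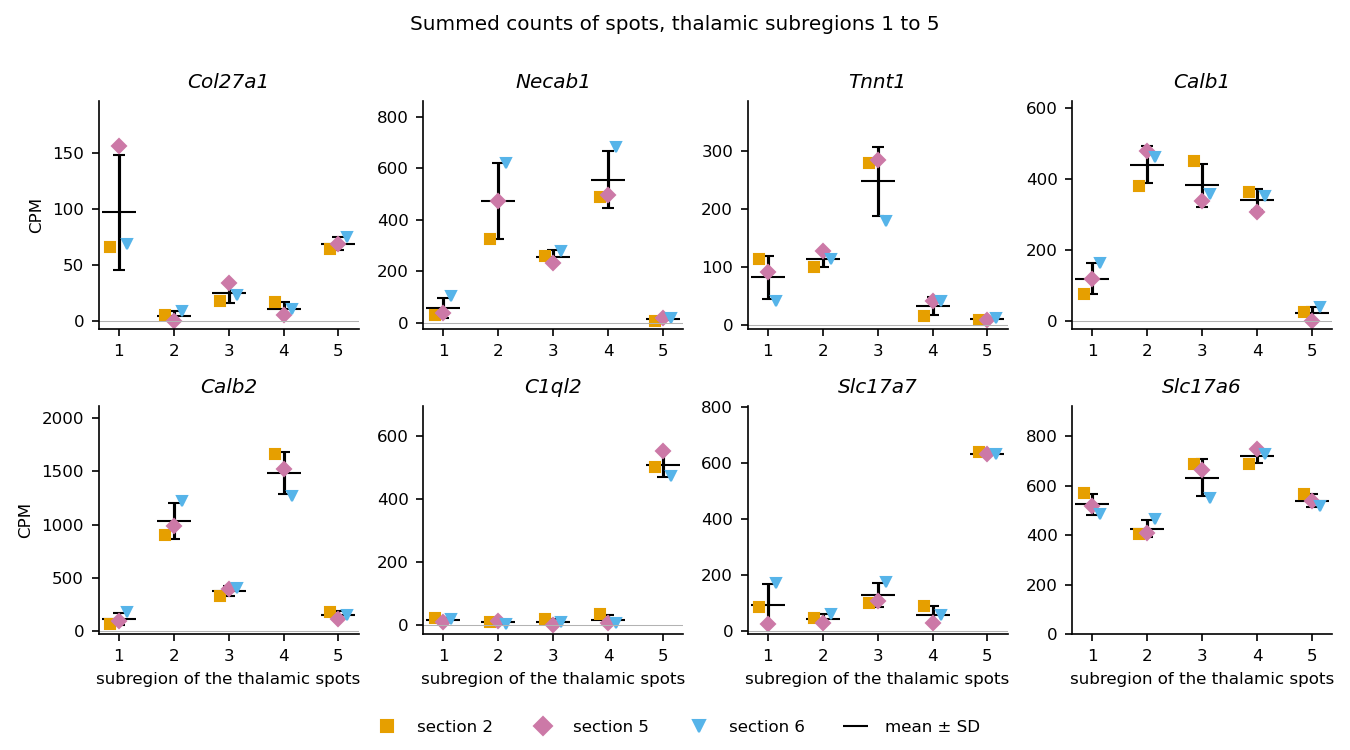
Expression of 8 genes, in CPM, in thalamic subregions 1 to 5; each point is 1 section, horizontal lines give the mean and error bars the SD over 3 sections. C1ql2 stood at 509.8 CPM in subregion 5 against 12.9 CPM as the mean of the others, and Col27a1 at 96.9 CPM in subregion 1.

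The sections are separate libraries from the single cells, which allowed the question whether the genes of a cell cluster were also higher in a subregion. Over 6067 genes tested in both, one-sided Fisher's exact test was used on genes with a log2 fold change of at least 1. The test treats genes as independent, so its p-values measure no spread between animals or sections. Cluster 1 shared 43 of 55 genes (78.2% against 4.57% of other genes, odds ratio 74.5, adjusted p = 6.49e-45) with subregion 1, among them Car4 and Col27a1. Cluster 2 shared 56 of 268 genes (20.9% against 1.86% of other genes, odds ratio 13.9, adjusted p = 1.07e-35) with subregion 3, Tnnt1 among them. It also overlapped with subregion 4 (15.7% against 4.60%, adjusted p = 6.08e-11), subregion 2 (14.6% against 3.69%, adjusted p = 8.28e-12) and subregion 1 (10.4% against 5.00%, adjusted p = 0.000650). The shares of different subregions were not tested against one another. Cluster 3 shared 60 of 91 genes (65.9% against 4.17% of other genes, odds ratio 44.4, adjusted p = 2.75e-56) with subregion 4 and 57 of 91 genes (62.6% against 3.28% of other genes, odds ratio 49.3, adjusted p = 1.16e-56) with subregion 2, Calb2 and Necab1 in both. Cluster 4 shared 186 of 404 genes (46.0% against 4.98% of other genes, odds ratio 16.3, adjusted p = 7.91e-109) with subregion 5, including C1ql2, Chrm1 and Slc17a7. Subregion 3 also took in 27.3% of the genes of cluster 1 (2.48% of other genes, adjusted p = 1.85e-11) and 24.2% of those of cluster 3 (2.38%, adjusted p = 3.66e-15). Spearman's rho of the log2 fold changes across genes, which are not independent replicates, was 0.40, 0.36, 0.27, 0.29 and 0.47 for these 5 pairs.

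The numbers shared moved with the animals. Without animals 1, 2 and 3, cluster 1 shared 83 of 138, 10 of 14 and 13 of 15 genes with subregion 1. Cluster 2 shared 74 of 433, 29 of 75 and 36 of 115 with subregion 3. Cluster 3 shared 94 of 199, 21 of 28 and 22 of 33 with subregion 4 and 87 of 199, 21 of 28 and 24 of 33 with subregion 2. Cluster 4 shared 223 of 592, 134 of 219 and 106 of 187 with subregion 5. Each of these passed in one-sided Fisher's exact test, with adjusted p at most 7.26e-10. The share of cluster 2 genes was 38.7% without animal 2 and 13.3% without section 5.

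Of the genes of clusters 1 to 4, 58.6%, 35.4%, 39.5% and 22.1% were higher in the thalamic region as a whole, against 18.6%, 18.2%, 18.6% and 18.7% of other genes (one-sided Fisher's exact test, adjusted p = 3.70e-13, 4.33e-16, 8.56e-08 and 0.0371). Without animal 1 the values for clusters 1 and 3 were 38.3% and 24.8%, and without animal 2 that for cluster 2 was 58.9%. Without animal 1, animal 3 or section 2 the value for cluster 4 was 18.2%, 23.8% and 17.4% and did not pass (p = 0.464, 0.0836 and 0.114, one-sided Fisher's exact test). Of the genes of clusters 1 to 4, 75.7%, 67.6%, 52.4% and 47.5% had a fold change above 0 in the region. For other genes these shares were 54.3%, 53.9%, 54.5% and 54.8%. The genes of clusters 3 and 4 thus leaned no more upward there than other genes. Spearman's rho of the log2 fold changes across all genes was 0.024, 0.057, -0.063 and -0.027.

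**Figure D4:**
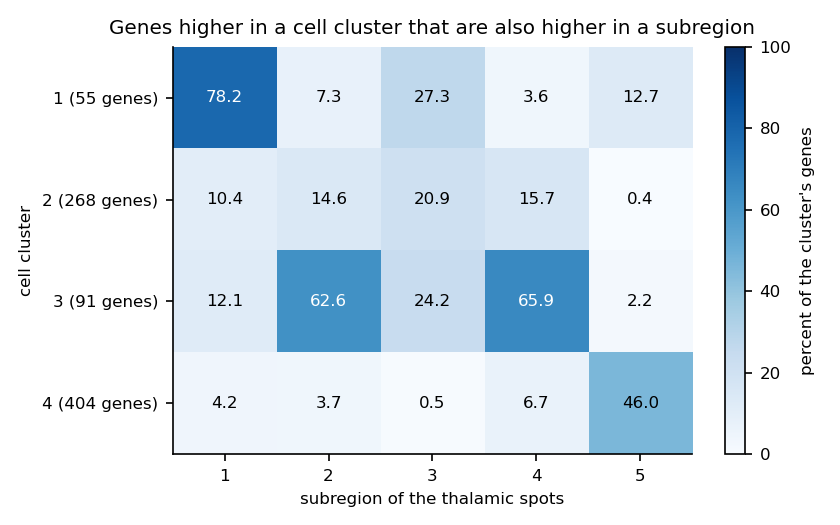
Percent of the genes called higher in each neuron cluster (vertical) that were also called higher in each thalamic subregion (horizontal). The highest values were 78.2% for cluster 1 in subregion 1, 20.9% for cluster 2 in subregion 3, 65.9% for cluster 3 in subregion 4 and 46.0% for cluster 4 in subregion 5.

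The anterior section was compared with the posterior ones to ask how the thalamic region changes along its length. There was 1 anterior section, so no test was made, and the exact Poisson 95% intervals cover counting error only. The genes are those at least 2-fold apart in the same direction in both posterior sections. Of 3958 genes with at least 50 counts, 4 were higher in the posterior sections, the haemoglobin genes Hba-a1 (chromosome 11, 32283672 to 32284486), Hba-a2 and Hbb-bs and the transthyretin gene Ttr (chromosome 18, 20664209 to 20674326). Hba-a1 was at 92.4 CPM (95% interval 74.4 to 113) in anterior section 5, 256 CPM (95% interval 235 to 279) in posterior section 2 and 478 CPM (95% interval 446 to 512) in posterior section 6. Ttr, an abundant transcript of choroid plexus, was at 307 CPM (95% interval 273 to 343), 1606 CPM (95% interval 1551 to 1662) and 801 CPM (95% interval 759 to 845) in the same order. Flywch1 was lower in the posterior sections, at 98.4 CPM (95% interval 79.8 to 120.1), 17.2 CPM (95% interval 12 to 23.9) and 43.9 CPM (95% interval 34.5 to 55), as was Arid4a at 61.9, 22.6 and 29.2 CPM. Prkcd stood at 93.4 CPM (95% interval 75.3 to 115), 115 CPM (95% interval 101 to 131) and 284 CPM (95% interval 259 to 311), and the intervals of sections 5 and 2 overlapped. Slc17a6 was at 518, 536 and 508 CPM, and Tcf7l2 at 733, 691 and 681 CPM. Outside the thalamic region the posterior over anterior ratio of Hba-a1 was 1.00 in section 2 and 1.54 in section 6, against 2.78 and 5.17 inside it. All 3 measured red blood cell genes and Ttr of 2 measured choroid plexus genes met the 2-fold criterion. With 1 posterior section alone, 12 genes met it for section 6 (without section 2), 7 of them higher and 5 lower in the posterior section. For section 2 (without section 6) 50 met it, 4 higher and 46 lower. The minimum of 50 counts was not met in every section, as section 2 held 35 counts of Flywch1 and 46 of Arid4a. With the minimum set on the mean of the sections, which was chosen after the data were seen, 5758 genes were compared. Of these, 7 were higher and 2 lower in both posterior sections.

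**Figure D5:**
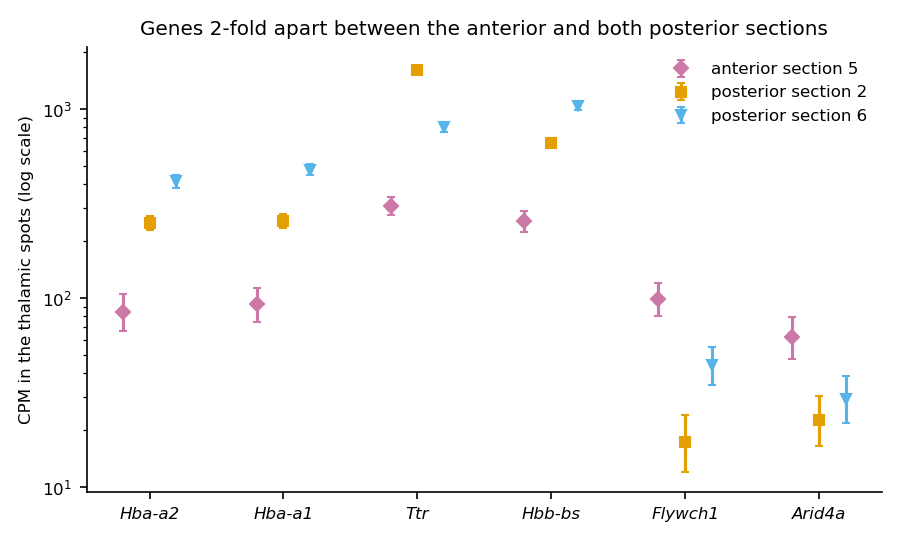
Expression of 6 genes in the thalamic region, in CPM on a log axis, in anterior section 5 and posterior sections 2 and 6; each point is 1 section and each bar its exact Poisson 95% interval. Hba-a1 was at 92.4 CPM in the anterior section and at 256 and 478 CPM in posterior sections 2 and 6, and Ttr at 307, 1606 and 801 CPM.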

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

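The tests of unequal subregion shares and of damage alone were chosen only after the result was seen, and the other tests in this part were written before it.

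Spike-in control wells should hold no mouse RNA, but on 1 plate of animal 2 the 4 such wells had a median of 17240.5 mouse counts (range 16224 to 18574). On 10 other plates 40 spike-in control wells had a median of 202 (40 to 829). The 4 wells meant for control RNA on that plate held a median of 141.5 counts (116 to 305), against 122321.5 on those 10 plates. Among those 10, the other plates of animal 2 were shallower. Their control RNA wells had medians of 16652, 22103 and 12948.5 counts and their spike-in control wells 84, 81.5 and 105.5. The comparison leaves out 3 plates of animal 1 whose cell wells had medians of 14, 21 and 11 counts, with medians of 15, 11.5 and 8 counts in spike-in control wells and 17, 73 and 12 in control RNA wells. The gene profile of the 4 wells was closer to control RNA than to the cells of the same plate, by a difference in rank correlation across genes of 0.3579 at the lowest and 0.3887 at the highest, which argues against carry-over from those cells and is consistent with the 2 kinds of control well having changed places. Whether any cell wells of the plate changed places too stays open, and no biological explanation was tested.

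A signal also lay in 9 wells that have 2 animals on record and entered no comparison, with a median of 30425 mouse counts (range 5093 to 202633). Which of the 2 records holds was not established.

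Cluster 2 cells held fewer counts than the other cells of the same animal (0.724, 0.719 and 0.609 of the animal's median) and a median mitochondrial share of 4.41%, against 3.24%, 1.99% and 2.36% in clusters 1, 3 and 4. With cells thinned to 5000 counts, 181 of 189 cluster 2 cells (95.767%) fell into 1 new cluster in which they were the majority. This argues against grouping by depth for these cells. The new cluster also held 32 cells of cluster 1 and 37 of cluster 3. Another 19 of the 208 cluster 2 cells were too shallow to be thinned and were left out, so the test does not cover them. In the test of damage alone, 20.896% of the genes of cluster 2 were higher in subregion 3 of the sections, against 1.86% of other genes. With 1 animal or section left out this share ranged from 13.3% to 38.7% and passed each time (adjusted p at most 2.03e-25, one-sided Fisher's exact test). Genes of cluster 2 were also enriched in subregions 1, 2 and 4 (10.4%, 14.6% and 15.7%), so the test does not tie the cluster to subregion 3, which did not come back on separate parts of the counts (8 of 148 spots). Genes of clusters 1 and 3 were enriched in subregion 3 as well. Damaged cells drawn from those clusters could give such an overlap, so the test cannot decide on damage alone. A part played by damage in the lower oxidative phosphorylation and ribosomal values of cluster 2 stays open, since neither test separates it from a difference between neurons.

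In the thalamic region, Hba-a1, Hba-a2, Hbb-bs and Ttr were higher in both posterior sections than in the anterior one. Outside the region the lowest posterior over anterior ratio of the 3 haemoglobin genes was 0.9991, in section 2, which argues against red blood cells spread evenly over the section. In section 6 the ratios there were 1.54, 1.45 and 1.40 for Hba-a1, Hba-a2 and Hbb-bs. Inside against outside the region, Hba-a1 was at 256 against 310 CPM in section 2 and 478 against 475 CPM in section 6. In anterior section 5 it was at 92.4 against 309 CPM. The difference can thus also be read as a low value in the anterior thalamic region. With the 5 subregions weighted equally the lowest ratio of the 3 genes stayed at 2.2405. For Ttr, the summed counts of the other 8 leading genes of the Ttr-rich spots were also higher in the posterior thalamic spots, by 3.40 (95% interval 2.17 to 5.59) and 1.7023 (1.04 to 2.90). This is consistent with choroid plexus tissue or its free RNA in those spots. The position along the nuclei, blood left in vessels and the preparation of each section stay open, and with 1 anterior section none of them can be separated.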

How the results depend on the processing

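The tests on cells with at least 2000 genes, without the doubtful plates, on separate parts of the counts, per plate, without cells of other types and with equal subregions were chosen only after the result was seen. RLE scaling left all 248 single-cell and 129 subregion calls on named genes in place. No low-count filter left 245 and 128, DESeq2 240 and 107, and no block 235 and 115. With clusters and tests on separate parts of the counts, 209 of 228 single-cell calls stayed. Of 46 subregion calls that could be tested there, 25 stayed and 15 were lost, and 7 of 54 named values turned direction. Leaving out animal 1, 2 or 3 left 248, 125 and 101, the last of 231 that could be tested, and leaving out section 2 or 6 left 98 and 112 of 126. All 30 calls on named genes of the thalamic region passed in each of its 8 alternative settings. Cluster 4 rests on 6, 9 and 24 cells, and simulated 2-fold changes of well-expressed genes were recovered there in 25% of cases. Where a count moved, the cause was not tested.

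With 1 animal left out, the number of genes ranged from 25 to 729 for cluster 1, 274 to 3706 for cluster 2, 41 to 944 for cluster 3 and 539 to 3564 for cluster 4, and from 20 to 1334 for clusters 1 and 2, 26 to 857 for clusters 1 and 3, 173 to 2416 for clusters 1 and 4, 45 to 2177 for clusters 2 and 3, 705 to 4512 for clusters 2 and 4, 140 to 1695 for clusters 3 and 4. With 1 section left out it ranged from 413 to 459 for subregion 1, 199 to 320 for subregion 2, 141 to 166 for subregion 3, 311 to 447 for subregion 4, 540 to 665 for subregion 5 and 3402 to 3776 for the thalamic region. List calls ranged from 19 to 33 with 1 animal left out. The anterior-posterior count was 12 and 50 with 1 posterior section left out.

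Without a low-count filter there were 363 for cluster 1, 416 for cluster 3, 389 for clusters 1 and 2 and 293 for clusters 1 and 3. Without the block there were 143 for clusters 1 and 2, 366 for subregion 1, 175 for subregion 2, 79 for subregion 3 and 355 for subregion 4. DESeq2 gave 372 for cluster 1, 2276 for cluster 2, 465 for cluster 3, 2627 for cluster 4, 626 for clusters 1 and 2, 416 for clusters 1 and 3, 1583 for clusters 1 and 4, 1187 for clusters 2 and 3, 1161 for clusters 3 and 4, 2635 for the thalamic region, 306 for subregion 1, 192 for subregion 2, 97 for subregion 3, 326 for subregion 4 and 554 for subregion 5. Sums of at least 10 cells gave 386 for clusters 1 and 2, 250 for clusters 1 and 3 and 841 for clusters 2 and 3. They left cluster 4 with the 1 sum of animal 3, which was assumed to vary like the others, and the counts that rest on it were 589 for cluster 4, 340 for clusters 1 and 4, 1186 for clusters 2 and 4 and 210 for clusters 3 and 4. Leaving out the doubtful plates gave 138 for clusters 1 and 2, and resolution 1.0 gave 904 for cluster 2 and 101 for clusters 1 and 2. Sums per plate, which treat plates of 1 animal as replicates, gave 992 for cluster 1, 3485 for cluster 2, 1040 for cluster 3, 1711 for clusters 1 and 2, 1072 for clusters 1 and 3, 1478 for clusters 1 and 4, 2560 for clusters 2 and 3 and 1071 for clusters 3 and 4. Clusters and tests on separate parts of the counts gave 339 for subregion 1 and 289 for subregion 5. A further fit, not among the alternatives fixed beforehand, pooled the other groups as 1, so that differences among them count as spread. It gave 3, 129, 8 and 732 genes for clusters 1 to 4 and 62, 1, 0, 35 and 462 for subregions 1 to 5. The gene lists called were 13 with an estimated correlation and 60 with fry, and a minimum of 200 counts left 2 genes in the anterior-posterior comparison.

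Values that turned direction were Calb2 in cluster 2 at resolution 1.0 (log2 fold change 1.57, adjusted p = 0.00808, against -0.01) and, on separate parts of the counts, Fbln1 (0.97), Foxp2 (1.38), AI504432 (0.75), Necab1 (0.51), Calb1 (0.65) and Slc17a6 (0.79) in subregion 1 and Gad2 (0.27) in subregion 5. On separate parts of the counts the group matched to subregion 1 took in 70 spots of subregion 3. The reference groups differed for subregions 1 and 5, so those values come from a different comparison. Prkcd in subregion 1, which did not pass with all sections (0.39), ranged from -0.94 to 0.84 with 1 section left out. The share of cluster 4 genes higher in the thalamic region ranged from 17.4% to 28.9% with 1 replicate left out.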

Other observations

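All tests in this part were chosen only after the result was seen, and the genes named here were chosen after their values were seen.

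Spots outside the thalamic region fell into groups with the genes of known forebrain tissues. Region 3 carried genes of striatal neurons, with Penk at 2225 CPM and Pde10a at 1254 CPM over all its spots. Region 4 carried the upper-layer cortical gene Lamp5 (504 CPM), and region 5 the myelin gene Mobp (5182 CPM). Region 9 carried hypothalamic hormone genes, with Oxt at 5406 CPM and Avp at 1500.5 CPM. Region 10 was led by Ttr at 95427 CPM together with Kl (845 CPM) and Clic6 (708 CPM), genes of choroid plexus. Region 11 had Pvalb at 2966 CPM and Six3 at 595 CPM, genes of GABA neurons such as those of the thalamic reticular nucleus. Region 2 was led by Lhx8 (40.8 CPM) and Slc5a7 (57.1 CPM), genes of cholinergic neurons. Region 12, with Cabp7 at 332 CPM and Neurod6 at 374 CPM, was found in section 6 only, in 60 spots.

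The oligodendrocyte-like cells of cluster 5 had Mobp at 3829 against 5.54 CPM in the other clusters and Opalin at 1781 against 0.226 CPM. At resolution 1.0 the thalamic spots fell into 10 groups, and 1 group of 8 spots was led by Tac2 (1931 CPM) and Pou4f1 (310.1 CPM), genes of the medial habenula. All 8 of these spots lay in subregion 3, which was itself led over its pooled spots by Tac2 (141 CPM). Another group was led by Prkcd (556 CPM) and 1 more by Calca (123.4 CPM), Tnnt1 (284 CPM) and Cbln1 (528 CPM). A group with Pvalb (304 CPM) and Gad1 (159 CPM) among its leading genes drew spots from subregions 1 to 4. The group led by C1ql2 (464 CPM) matched subregion 5. In sections 2, 5 and 6, subregion 2 held 55, 9 and 4 spots of a group led by Gda and 0, 32 and 30 of a group led by Oxt. Subregion 4 held 34, 2 and 4 spots of a group led by Rab3b and 1, 35 and 30 of a group led by Foxp2. Both subregions thus differed in make-up between section 2 and the other sections. Cluster 1 was led over its pooled cells by the smooth muscle genes Acta2 (172 CPM), Myl9 and Myh11, and for each gene the 5 highest of 439 cells held 98.9%, 98.7% and 98.8% of the counts. Reporter sequences gave 22 counts over 1216 cell wells, under the 32.6 counts that 112 control wells without a count allow.

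Group labels of the sums were exchanged within each animal or section, in 50 splits of the cell clusters and 100 of the subregions. The same counts defined and tested the groups, so a high number of genes in the real split was fixed beforehand, and these splits leave open whether chance is excluded. The numbers were 146 for cluster 1 (highest of the other splits 7), 1410 for cluster 2 (939), 189 for cluster 3 (40) and 1569 for cluster 4 (1126). They were 216 for clusters 1 and 2 (87), 150 for clusters 1 and 3 (11), 826 for clusters 1 and 4 (237), 523 for clusters 2 and 3 (353), 2182 for clusters 2 and 4 (1641) and 560 for clusters 3 and 4 (563, with 2 of 50 splits as large, the real one included). For the subregions they were 663 for subregion 1 (296), 467 for subregion 2 (127), 261 for subregion 3 (42), 607 for subregion 4 (207) and 880 for subregion 5 (625). Chance could not be excluded for the number of gene lists called between clusters, where 6 of 50 splits, the real one included, gave as many (30, highest other 34). The thalamic region allows 4 splits, too few for a share under 0.05, with 4324 genes in the real one and 0 as the highest other.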
